A study of Mus musculus with 2 samples.

How the data were processed

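Chromatin accessibility was measured by ATAC-seq in cultured cells of 2 mouse glioma lines, PPO1 and PPO2, with 1 sample per line and 2 peak lists per sample. Nothing in the labels says whether the lists of a sample come from separate cultures or from a repeated library, so they were counted as 1 replicate. The labels give the line and the genotype, with floxed Pten and Trp53 alleles and an Olig1 Cre (PPO1) or Olig2 Cre (PPO2). The titles of the deposited lists and the sample labels disagree: each sample holds lists titled with the name of the other line. The assignment follows the sample that holds each list and that sample's label, and every direction between the lines reverses if the titles are right.

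Per the submitters' processing notes, the authors used cutadapt, Bowtie2 and Picard, without versions, and the genome build mm10. The peak caller, its settings, the removal of duplicate or mitochondrial reads, any shift of reads for the transposase offset, any filter on repeat-rich regions and any pooling before peak calling are not given in the sources used here. Such steps set how many peaks pass a threshold, so list length cannot be read as a measure of accessibility. The deposited lists have no header and follow the 9-column broad peak layout. From that layout and the values, the authors' score per peak is 10 times the −log10 of the q-value, cut to a whole number, in over 99.9% of lines. The deposited fold enrichment is the ratio of the peak's signal to the background estimated by the peak caller. The deposited lists also give a −log10 p-value and a −log10 q-value per peak, and the lowest −log10 q was just above 1 in each list. The lists hold peaks on 21 chromosomes and none on mitochondrial or unplaced sequences. The peak numbering skips 2 numbers in each list. Score, fold and q are the authors' own values and were used only to describe, rank or filter peaks within a list.

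Depth was unknown, since the lists give no read counts. The number of peaks per list, 34261 to 48015, sets the precision of shares, given as Wilson 95% intervals that cover counting error only. Neighbouring regions and genes are not replicates. With 1 sample per line no test between lines was possible.

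Peaks were compared with bedtools 2.31.1 in Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9), with an overlap of at least 1 bp. Touching or overlapping peaks of the 4 lists were merged into regions. A region was PPO1-only if both PPO1 lists and no PPO2 list had a peak in it, PPO2-only in the mirror case, common if all 4 lists had one, and mixed otherwise. Positions of 21887 protein-coding genes came from RefSeq on GRCm38.p6, the assembly of mm10. The table used gives gene starts and ends without strand, exons or sequence. The planned distance to a transcription start was therefore replaced by the distance to the nearer of both annotated gene ends, so a gene end may be the 3′ end. Regions within 1 kb of an end count as gene-end regions, and line-only regions were assigned to the gene with the nearest end within 50 kb. The planned split into exons and introns and the planned motif search were not run, because both need strand-aware annotation or the genome sequence, which were not used here.

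Before the data were examined, 18 gene lists were fixed: OPC, oligodendrocyte, transit-amplifying, astrocyte, neural stem, neuron, microglia, endothelium and pericyte, mesenchymal, cell cycle, receptor tyrosine kinase, p53 target, forebrain patterning, posterior Hox, Hippo target, Notch, housekeeping and immediate early genes. They had 250 entries, all matched to a gene position except Cyr61, an older name of Ccn1, which the same list holds. Some genes belong to more than one list. For each list the mean of PPO1-only minus PPO2-only regions per gene was placed as a percentile among 10000 random lists of the same size, matched on the mean number of assigned peaks. A list was called outside below percentile 2.5 or above 97.5. On simulated data, all of 5000 peaks received their known class (100%), and 11 of 200 unchanged lists drawn over 21887 genes fell outside the central 95%. A raised and a lowered list reached percentiles 100 and 0. The simulated lists held genes drawn singly, so this check does not cover lists of neighbouring genes. The simulated peaks were slightly shifted copies of the same peaks, equal in width in every list that held them. Classing was thus not checked for peaks that bridge neighbours, differ in width between lists or lie near a threshold.

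The genes and regions named were chosen by a rule fixed before the data were examined. It took the targeted and driver genes, the 12 genes per line with the most unequal count among genes with at least 5 line-only regions, ranked by a standardised difference from the genome-wide share, list members with a gene end open in both lists of 1 line and no list of the other, and the 3 strongest line-only regions per line. Ties went by symbol. Other list members and genes given as examples were chosen after their values were seen.

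Alternatives fixed beforehand were the stronger 50% of each list by q, an equal number of strongest peaks per list (34261, the length of the shortest), an overlap of 50% of the peak or of both peaks, 50% coverage of a region, merging of peaks within 200 bp, leaving out each list in turn, other gene-end windows, a reach of 10 or 100 kb, and all annotated genes. Added after the data were seen were assignment to the nearest gene span, a balance relative to the gene's own chromosome, gene-end and other regions apart, and leaving out genes on chromosomes 15 and 18.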

Results

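The data describe open chromatin in a pair of mouse glioma cell lines, measured by ATAC-seq, in which a transposase cuts and tags accessible DNA. The line PPO1 carries floxed Pten and Trp53 alleles with an Olig1-driven Cre, and PPO2 carries the same floxed alleles with an Olig2-driven Cre. Pten is a lipid phosphatase that restrains PI3-kinase signalling and Trp53 encodes p53; both are tumour suppressors. Olig1 and Olig2 are transcription factors of the oligodendrocyte lineage. The cells grew in serum-free medium with FGF and EGF, and the series' title places the work in the question of how progenitor states of the lineage bear on glioma formation after loss of both genes. There was 1 sample per line, each with 2 peak lists. The lists are called PPO1 list 1 and list 2, and PPO2 list 1 and list 2, and count as 1 replicate per line. No difference between the lines has a replicate check, so no p-value is given, and 95% intervals (Wilson) cover counting error only. The lists of each line carry the other line's name in their own titles. They were assigned by the sample that holds them, so "PPO1" stands for the library labelled PPO1 throughout, and every direction would turn if those titles were right.

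Most of the open chromatin of the library labelled PPO2 was also open in the library labelled PPO1, and PPO1 had many further peaks. The PPO1 lists held 48015 and 47206 peaks and the PPO2 lists 34371 and 34261, a ratio of 1.39 between the means. Covered length was 23.0 and 22.4 Mb in PPO1 and 17.2 and 16.8 Mb in PPO2. Median peak width was 379 and 374 bp in PPO1 and 411 and 406 bp in PPO2, and the median fold enrichment, the authors' own value per peak, was 4.34, 4.38, 4.31 and 4.32. On average 80.5% of PPO2 peaks overlapped a peak of a PPO1 list, and 58.2% of PPO1 peaks overlapped a peak of a PPO2 list. The lists of the same line overlapped by 87.4% (PPO1) and 86.8% (PPO2). The Jaccard index of covered bases was 0.694 and 0.654 within a line and 0.475 to 0.483 between lines. The number of reads behind each list is unknown. When every list was held to its 34261 strongest peaks, the overlap between lines was 69.2% of PPO1 peaks and 69.3% of PPO2 peaks.

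The targeted genes and the Cre driver genes were open at a gene end in both libraries. Pten (chromosome 19, 32757577–32826160, mm10) had 1 region common to all 4 lists at its lower-coordinate end (32755977–32758184), with fold enrichment of 5.00, 4.28, 4.06 and 4.02 in PPO1 lists 1 and 2 and PPO2 lists 1 and 2. A further region inside Pten (32792663–32792932) was listed in both PPO1 lists and in no PPO2 list. Trp53 (chromosome 11, 69580348–69591873) had 3 common regions in or within 10 kb of the gene, and 2 of them lay at least partly inside it (69579915–69580505 and 69581071–69581674). Olig1 (chromosome 16, 91269769–91271939) and Olig2 (chromosome 16, 91225550–91228677) each had 3 common regions, including one over an end of the gene. The labels do not name the deleted exons, and accessibility outside a deleted part says nothing about the deletion, so these regions do not check the genotypes or the labels.

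Regions found in all 4 lists lay at gene ends more often than all other regions, whether of a single line or mixed. The 4 lists merged into 60646 regions. Of these, 24614 were common to all 4 lists, 12849 were PPO1-only (both PPO1 lists and no PPO2 list), 3537 were PPO2-only and 19646 were mixed. Among common regions 42.3% (41.7–42.9) lay within 1 kb of an end of a protein-coding gene, against 8.18% (7.72–8.67) of PPO1-only, 8.06% (7.21–9.0) of PPO2-only and 8.56% (8.17–8.96) of mixed regions. The 6111 mixed regions found in lists of both lines had 12.6% (11.7–13.4) at gene ends. Common regions were also wider, with a median of 726 bp against 317 bp (PPO1-only), 344 bp (PPO2-only) and 259 bp (mixed). Merging peaks of 4 lists widens common regions by construction, so width decides nothing here. Their median −log10 q was also higher, 4.81 and 4.75 in the PPO1 lists and 3.32 in both PPO2 lists. The medians were 2.56 and 2.55 for PPO1-only, 2.26 and 2.19 for PPO2-only and 1.90 to 2.19 for mixed regions. The contrast thus goes with peak strength and detection in every list, and not with sharing between lines alone. Gene bodies held 41.9% (41.1–42.8) of PPO1-only and 51.1% (49.5–52.8) of PPO2-only regions, and 49.9% (49.0–50.8) and 40.8% (39.2–42.4) lay between genes. By gene, 11403 of 21887 protein-coding genes had a peak at either end in each of the 4 lists, not necessarily at the same end. Counted in the same way, 670 had a PPO1-only gene end and 197 a PPO2-only one. PPO1-only regions made up 78.4% (77.8–79.0) of 16386 line-only regions. With 34261 peaks per list there were 5953 PPO1-only and 5960 PPO2-only regions, counts that lists of equal length force close together. The gene-end counts became 318 genes (315 of them among the 670) and 481 genes (195 among the 197). That setting drops peaks almost only from the PPO1 lists, so PPO2-only gene ends could hardly be lost and PPO1-only ones hardly gained. The share in gene bodies was again higher for PPO2-only regions there, at 49.0% against 40.7%. This adds little support, since that setting keeps nearly all PPO2-only regions of the full lists. With the stronger 50% of each list, 22.1% of PPO1-only and 9.70% of PPO2-only regions lay at gene ends. There 1281 genes had a PPO1-only gene end, most of them not PPO1-only in the full lists. That setting kept 24007 and 23603 PPO1 peaks against 17185 and 17130 PPO2 peaks. A gene end with a weaker PPO2 peak can thus be classed as PPO1-only there. Without PPO2 list 1 or list 2, when a single PPO2 list defined the class, PPO2-only regions numbered 5607 and 5720.

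By the authors' q-values, the strongest regions of a single line lay away from gene ends. Their order follows the higher −log10 q of the line's 2 lists. By the lower value, Sumf1 (7.13) would stand before Srgap3 (4.98), and the chromosome 16 region (9.07) before that of chromosome 13 (8.83). In PPO1 the leading region (chromosome 8, 109745890–109746156) was between genes, 8228 bp from Atxn1l, with fold enrichment of 8.30 and 9.55. The next were inside 2210408I21Rik (chromosome 13, 77610809–77611031; 9.10 and 7.47) and between genes on chromosome 16 (86473386–86473702; 7.47 and 9.10), 572418 bp from the nearest gene, Adamts5. In PPO2 all 3 lay inside genes, namely Srgap3 (chromosome 6, 112838895–112839299; 5.51 and 7.16), which encodes a GTPase-activating protein, Sumf1 (chromosome 6, 108145870–108146232; 6.43 and 6.73) and Rasal2 (chromosome 1, 157143339–157143638; 5.39 and 6.85). Exon or intron was not assigned, since exon positions were not used here.

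Of 18 gene lists fixed before the data were examined, 3 stood outside the central 95% of 10000 random lists. The random lists were matched on the number of assigned peaks, and 0.9 lists would be expected outside by chance. This expectation holds for genes drawn singly over the genome. The Hox genes lie in clusters, where neighbours can share a local shift, so their percentile cannot be taken at face value. Mesenchymal genes had 25 PPO1-only and 2 PPO2-only regions (percentile 99.5). Genes of the posterior Hox list had 11 and 0 (percentile 99.8). Hox genes pattern the body axis, and despite its name the list also holds anterior and central ones, such as Hoxa1 and Hoxc6. Receptor tyrosine kinase genes had 8 and 8, the lowest balance relative to random lists (percentile 0.865). A single gene, Ntrk2, held 4 of the 8 PPO2-only regions. All 3 calls ended when the lists were held to equal numbers of peaks, with 7 and 7 regions for the mesenchymal list (percentile 54.7), 4 and 1 for the Hox list (94.9) and 5 and 10 for the kinase list (12.5). The astrocyte list alone was then outside, with 4 PPO1-only and 14 PPO2-only regions (percentile 0.535), against 12 and 9 (percentile 7.64) in the full lists, and it also lay outside without PPO2 list 1 (1.74) and relative to each gene's chromosome (0.62). It lay inside under the other settings, among them 91.2 with the stronger 50% of each list, 33.2 without PPO2 list 2 and 29.7 with a reach of 10 kb. The mesenchymal call also ended with the stronger 50% of each list (17.3), a reach of 10 kb (96.1) and all annotated genes (96.5), and the Hox call without genes on chromosomes 15 and 18 (96.2). The kinase call also ended with the stronger 50% (6.09), without PPO1 list 2 (11.8) or PPO2 list 1 (4.11), with a reach of 10 or 100 kb (46.9 and 2.63) and with all annotated genes (8.9). These percentiles describe the libraries and are not tests of the lines.

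Among the 20 mesenchymal genes, 13 had a PPO1-only region. Runx1, a transcription factor best known from blood formation, had 4, and Anxa2, a calcium-dependent membrane-binding protein (chromosome 9, 69453683–69491792), also had 4, one of them over its lower-coordinate end (69453421–69453784). Tgfbi, an extracellular matrix protein, had 3. Stat3, Spp1 (osteopontin), Serpine1 (an inhibitor of plasminogen activators) and Anxa1 had 2 each. The 2 PPO2-only regions of the list were near Vim (vimentin) and Cebpb. With equal numbers of peaks, Runx1, Stat3 and Spp1 had no line-only region, Anxa2 and Anxa1 had 1 PPO1-only region each, Serpine1 had 2, and Tgfbi had 1 PPO1-only and 2 PPO2-only regions. In the Hox list 9 of 24 genes had a PPO1-only region, and 7 had a PPO1-only gene end (Hoxa3, Hoxa7, Hoxa10, Hoxc6, Hoxc8, Hoxd3 and Hoxd8). Of these, Hoxa3, Hoxa10 and Hoxc6 held with equal numbers. None of the 8 Hoxb genes of the list had a gene-end peak in any list.

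In the astrocyte and kinase lists, Ntrk2, Aldh1l1 and Aqp4 had PPO2-only and no PPO1-only regions both in the full lists and with equal numbers of peaks. Holding lists to 34261 peaks leaves the PPO2 lists (34371 and 34261 peaks) almost whole and shortens the PPO1 lists. A PPO2-only region could therefore hardly be lost in that setting, or a PPO1-only one gained. Agreement between the settings on PPO2-only regions was nearly fixed beforehand and adds no support. Ntrk2, the receptor of BDNF (chromosome 13, 58806472–59133970), had 4 PPO2-only and 0 PPO1-only regions in both settings. In the full lists they lay at 58841048–58841429, 59091471–59091989 and 59092548–59093065 inside the gene and at 59145765–59145962 beyond it, while its gene end was open in all 4 lists. Aldh1l1, a folate enzyme and marker of astrocytes (chromosome 6, 90550768–90599171), had 3 PPO2-only and 0 PPO1-only regions, including one at its lower-coordinate end (90550644–90550870), and 4 and 0 with equal numbers. Aqp4, the water channel of astrocytes, had 2 and 0 in both and no gene-end peak. Slc1a3, an astrocytic glutamate transporter, went from 3 PPO1-only and 0 PPO2-only regions to 2 and 3, and Nfia from 5 and 2 to 0 and 2. S100b had a PPO1-only gene end that did not hold with equal numbers. Clu and Egfr also had PPO2-only and no PPO1-only regions in both settings (1 in both for Clu, 1 and then 2 for Egfr), while Aldoc, Id3, Fgfr2 and Erbb4 had 1 PPO1-only and 0 PPO2-only regions in both.

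**Figure D1:**
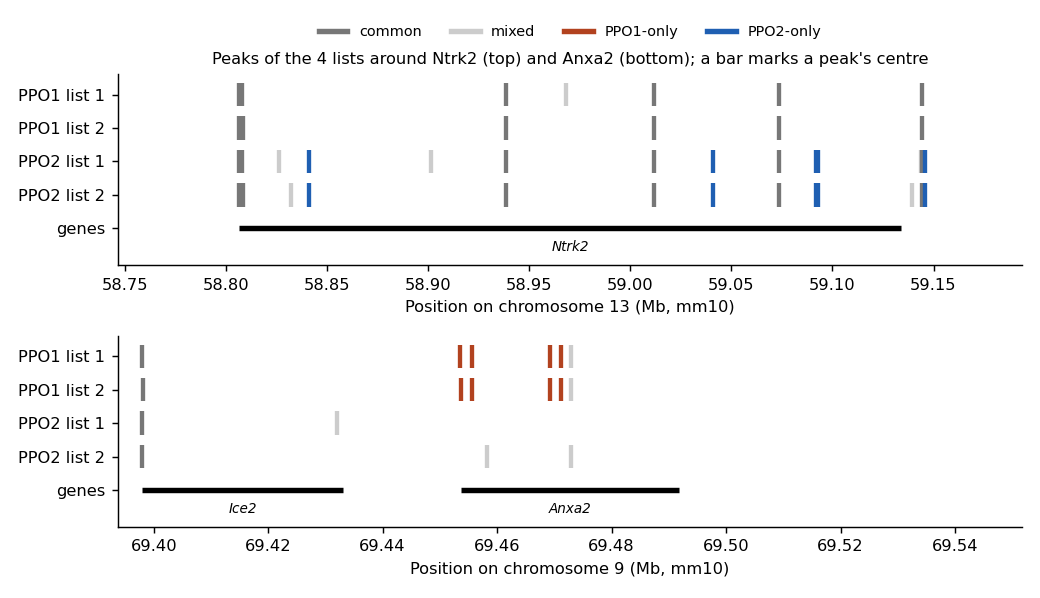
Peaks of the 4 lists (rows) by position in Mb (mm10) around Ntrk2 on chromosome 13 and Anxa2 on chromosome 9; each bar marks the centre of a peak, its colour the class of its region, and black lines the annotated genes. Ntrk2 shows 5 PPO2-only peaks in each PPO2 list, of which 4 lie within 50 kb of a gene end and were assigned, and Anxa2 shows 4 PPO1-only peaks in each PPO1 list.

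The other lists lay inside the central 95% of random lists in the full lists. Single settings put 4 of them outside: the stronger 50% of each list for oligodendrocyte genes (percentile 0.295), all annotated genes for Hippo targets (0.765), and the loss of PPO2 list 2 for neural stem (1.45) and immediate early genes (1.24). In the full lists, progenitor and lineage lists had more PPO1-only than PPO2-only regions, as did the genome: 15 and 4 for oligodendrocyte precursor (OPC) genes (percentile 50.4), 5 and 2 for oligodendrocyte genes (25.2), 10 and 2 for genes of transit-amplifying cells (51.2), 8 and 4 for neural stem genes (8.99) and 9 and 5 for neuronal genes (29.1). Lists for other cells of the brain gave 5 and 2 for microglia (71.8) and 9 and 1 for endothelium and pericytes (91.4). Signalling and patterning lists gave 10 and 2 for Notch (44.2), 8 and 3 for Hippo targets (27.3) and 7 and 3 for forebrain patterning (30.3). Remaining counts were 7 and 2 for the cell cycle (23.8), 6 and 1 for p53 targets (43.0), 5 and 3 for immediate early genes (8.89) and 8 and 0 for housekeeping genes (87.6). Held to equal numbers of peaks, several of these turned or evened out, with 2 and 7 for OPC, 2 and 5 for oligodendrocyte, 3 and 4 for transit-amplifying, 5 and 7 for neural stem, 4 and 7 for Notch and 2 and 5 for forebrain patterning genes. Counts were even for neuronal (5 and 5), cell cycle (4 and 4) and immediate early genes (3 and 3). PPO1-only regions stayed more numerous for microglia (4 and 3), endothelium and pericytes (5 and 3), Hippo targets (6 and 4), p53 targets (4 and 1) and housekeeping genes (3 and 1). Over the genome, equal numbers moved the ratio of PPO1-only to PPO2-only regions from 3.63 to 0.999. The turned and even counts can therefore not be read as particular to these lists. Against matched random lists, all of them then lay inside the central 95%, with percentiles from 9.905 (OPC) to 86.745 (p53 targets).

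**Figure D2:**
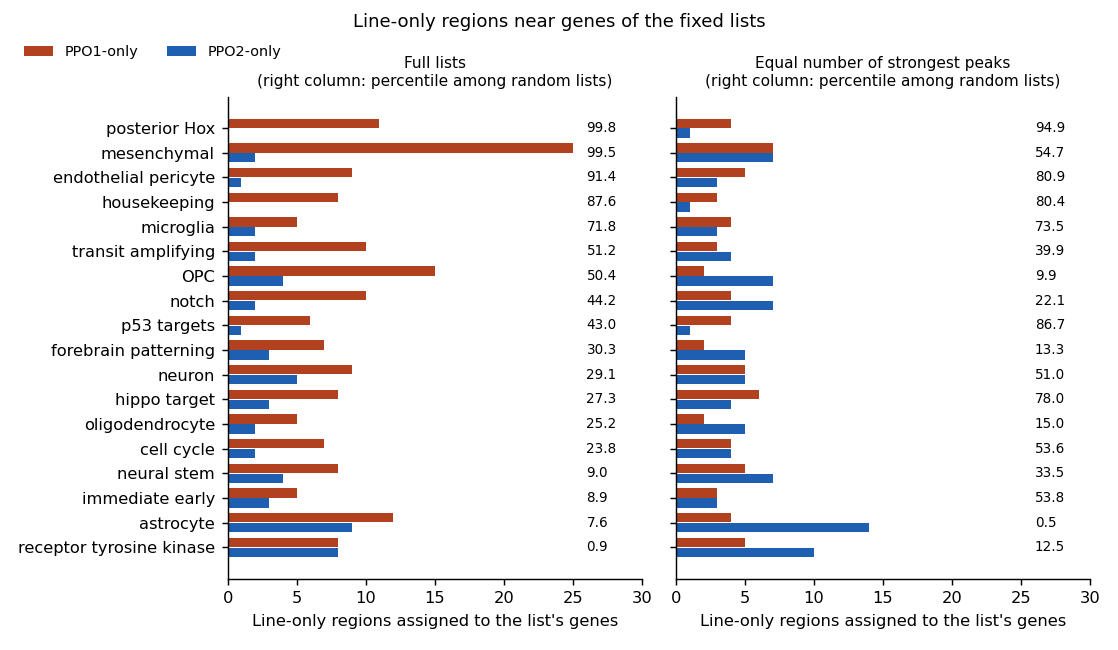
Number of PPO1-only and PPO2-only regions assigned to the genes of each fixed list (x axis, regions) for the full lists (left) and for 34261 strongest peaks per list (right), with the percentile among 10000 matched random lists beside each pair of bars. The mesenchymal, posterior Hox and kinase lists stand outside the central 95% on the left only, and the astrocyte list on the right only.

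At gene ends, 24 list members differed between the lines in the full lists, 22 PPO1-only and 2 PPO2-only, whereas with equal numbers of peaks 7 were PPO1-only and 9 PPO2-only. Besides the Hox genes these included Nes, the intermediate filament nestin of neural progenitors, the transcription factors Dlx1, Sp8 and Insm1 of the transit-amplifying list, Dlx5 and Lhx6 of the forebrain list, the OPC-list matrix genes Matn4 and Vcan, the receptors Notch3 and Fgfr3, the AP-1 subunit Fosl1, Bbc3 (the p53 target Puma), Tmem119, S100b and Anxa2. With equal numbers of peaks 7 of the 22 held, namely Nes, Dlx1, Sp8, Tmem119, Hoxa3, Hoxa10 and Hoxc6. The PPO2-only gene ends were those of Aldh1l1 and Neu4, a sialidase gene of the OPC list. Both held with equal numbers, but that setting shortens almost only the PPO1 lists, so they could hardly be lost. The other PPO2-only gene ends with equal numbers were those of Slc1a3, Gja1, Neurod6, Eomes, Flt1, Emx2 and Arx. None of these was PPO2-only in the full lists. There Slc1a3, Gja1, Flt1, Emx2 and Arx had a gene-end peak in all 4 lists, and Neurod6 and Eomes were mixed. Their class changed because the setting drops weaker PPO1 peaks, so they are not gene ends open in PPO2 alone. No list had a gene-end peak at Pdgfra, Sox10, Gpr17, Pcdh15, Gfap or Aqp4, while Olig1, Olig2, Sox2, Ascl1 and Egfr had one in all 4. The housekeeping genes Actb and Ywhaz had none in any list either, so a missing gene-end peak does not by itself tell about lineage. A peak missing from a list was not detectable at a depth that is unknown, and is not evidence of closed chromatin.

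Ranked by how uneven their line-only regions were, single genes led toward PPO1 by number alone. Shb, an adaptor protein of tyrosine kinase signalling (chromosome 4, 45423276–45530828), had 7 PPO1-only and 0 PPO2-only regions. Nfib, a transcription factor of glial development (chromosome 4, 82290173–82506751), Deptor, an inhibitor of mTOR, Bcor, a transcriptional corepressor, Map4k4, a kinase, Il12a, a cytokine subunit, Adgrb3, Aebp2, Gask1b, Gipc2, Hpcal1 and the predicted gene Gm52720 had 6 and 0 each. Ties were taken by symbol, and 47 of the 109 genes with 5 or more line-only regions had PPO1-only regions alone. With equal numbers Shb and Nfib had 2 and 0, Deptor 3 and 0, Map4k4 4 and 1, and Bcor 4 and 4. The differences also moved under other settings. With all annotated genes in place of protein-coding ones, PPO1-only minus PPO2-only regions came to 0 for Nfib, 1 for Deptor and Hpcal1 and 2 for Bcor, Gipc2 and Gm52720, and with the stronger 50% of each list to 0 for Map4k4, Gask1b and Hpcal1. With a reach of 10 kb none of the 12 exceeded 2, and with 100 kb Nfib had 12.

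Toward PPO2, Sp110, a nuclear body protein (chromosome 1, 85570735–85610850), had 1 PPO1-only and 4 PPO2-only regions in the full lists and with equal numbers of peaks. Keeping the 4 is no further support, since equal numbers drop peaks almost only from the PPO1 lists. The difference of PPO1-only minus PPO2-only regions of Sp110, -3, was 0 with the stronger 50% of each list and -1 with assignment to the nearest gene span. Sp110 lies among related genes of the Sp100 family, where reads can be shared between copies, so its regions are uncertain. Acsf3, a mitochondrial acyl-CoA synthetase, had 2 and 3 and Adcy1, an adenylyl cyclase, 3 and 3, which became 1 and 3, and 0 and 4, with equal numbers. The others ranked toward PPO2 still had more PPO1-only than PPO2-only regions in the full lists, with 3 and 2 for Hhat, Kirrel, Kirrel3, Prkd1, Slc44a3, Timp3 and Tph2 and 4 and 2 for Kdm4b and Klf7. With equal numbers of peaks PPO2-only regions were more numerous for Kdm4b (0 and 2), for Klf7, Hhat, Kirrel3 and Slc44a3 (1 and 2 each) and for Tph2 (2 and 3). Kirrel and Prkd1 then had 2 and 2, and Timp3 had 3 and 2. Equal numbers moved the ratio of PPO1-only to PPO2-only regions over the genome from 3.63 to 0.999. These turns, with those of Acsf3 and Adcy1, can therefore not be read as particular to the genes.

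The balance between the lines differed from chromosome to chromosome. Chromosome 18 had the lowest share of PPO1-only among line-only regions, 53.3% (48.5–58.1; 217 PPO1-only and 190 PPO2-only), and chromosome 15 the highest, 89.9% (87.8–91.6; 850 and 96). Chromosomes 7 (62.6%, 58.8–66.2), 2 (65.5%, 62.6–68.3) and 12 (68.5%, 65.0–71.9) were also low, and chromosomes 3 (88.7%, 86.9–90.3) and 17 (87.2%, 84.6–89.4) high, against 78.4% over the genome. All peaks followed the same order at these extremes, since the ratio of PPO1 to PPO2 peaks was 1.05 on chromosome 18 and 1.79 on chromosome 15. With equal numbers of peaks the share was 25.3% (21.2–30.0) on chromosome 18, 27.9% (24.3–31.7) on chromosome 7 and 34.2% (31.2–37.4) on chromosome 2, against 65.8% (61.9–69.5) on chromosome 15, 67.5% (63.1–71.6) on chromosome 17 and 68.6% (65.4–71.5) on chromosome 3.

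**Figure D3:**
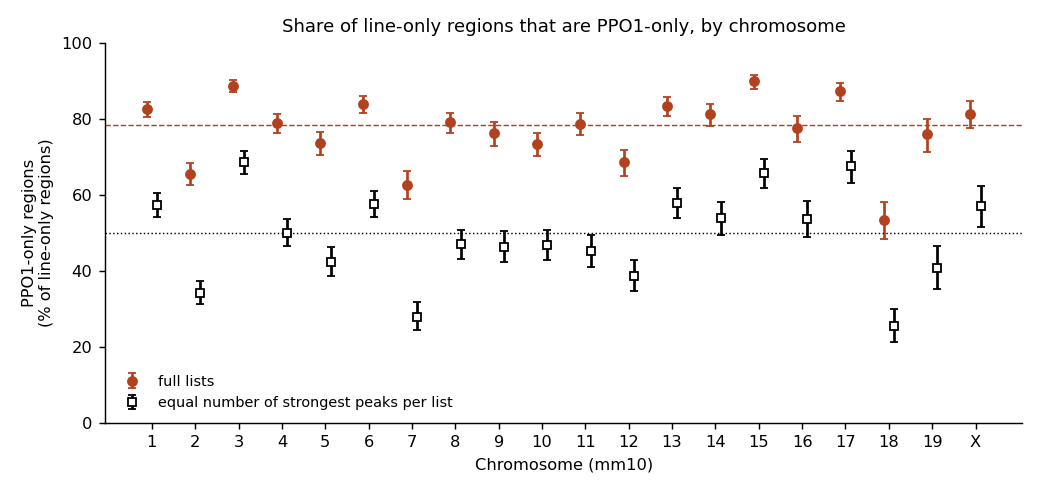
Share of line-only regions that were PPO1-only (y axis, percent) on each autosome and X, with Wilson 95% intervals, for the full lists (filled circles) and for 34261 strongest peaks per list (open squares); dashed and dotted lines give the genome-wide share of each. Chromosome 18 is lowest in both, at 53.3% and 25.3%, and chromosomes 15, 3 and 17 are the highest in both.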

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

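Assignment to the nearest gene span, the balance relative to a gene's chromosome, the split into gene-end and other regions and the removal of genes on chromosomes 15 and 18 were added after the data were seen. Peaks overlapped the other list of their line more often than the lists of the other line, and line-only regions lay at gene ends less often than common ones, under every setting run on them. Read depth is unknown, so no limit of detection can be given. The ratio of PPO1-only to PPO2-only regions was 3.63, and 0.999 with equal numbers of peaks, where equal lengths force it toward 1. The cause of the other changes was not tested, except where a setting keeps fewer peaks by construction. No paired analysis was possible because there is 1 sample per line and the labels give no replicate numbers. Keeping unplaced and mitochondrial sequences was not run, since the lists hold none, nor was any motif alternative, for which the genome sequence was not used here.

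With the stronger 50% of each list, covered length was 14.3, 13.9, 9.98 and 9.75 Mb (PPO1 lists 1 and 2, PPO2 lists 1 and 2). Mean overlap was 83.8% within PPO1, 79.3% within PPO2, 56.4% of PPO1 peaks in PPO2 lists and 78.2% of PPO2 peaks in PPO1 lists. There were 5705 PPO1-only, 1546 PPO2-only and 11246 common regions, gene-end shares of 58.9% (common), 22.1% (PPO1-only) and 9.70% (PPO2-only), and 1281 genes with a PPO1-only gene end, 139 of them among the 670. The mesenchymal list turned to percentile 17.3. With equal numbers the overlaps were 84.8% within PPO1, 69.2% of PPO1 peaks and 69.3% of PPO2 peaks. Regions were 5953 PPO1-only and 5960 PPO2-only, with gene-end shares of 46.8% (common), 7.36% and 10.3%. Genes with a line-only gene end were 318 (PPO1) and 481 (PPO2), the chromosome shares 25.3% (18) and 65.8% (15), and 1 list lay outside the central 95%, sharing 0 with the main 3.

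Requiring overlap of 50% of the peak gave 84.1%, 82.5%, 52.0% and 75.5% for the overlaps in the order above, and 50% of both peaks gave 80.5%, 78.2%, 48.6% and 67.4%. A narrower gene-end window gave gene-end shares of 39.9% (common), 5.97% (PPO1-only) and 6.02% (PPO2-only), and a wider one 46.7%, 13.0% and 12.7%. A reach of 10 kb left 1 list outside, one of the main 3. Gene-end regions alone gave 58.8% on chromosome 18 and 86.3% on chromosome 15. Leaving out each list in turn gave 4151 to 5720 PPO2-only regions, 5607 and 5720 of them without PPO2 list 1 and list 2. It gave gene-end shares of 40.4% to 41.4% (common) and 7.77% to 9.35% (PPO1-only), 47.2% to 61.5% on chromosome 18, 85.0% to 91.3% on chromosome 15, and 2 to 5 lists outside, with 5 without PPO2 list 2. Of the percentiles of single lists under these settings, 23 stayed outside the central 95% and 173 inside, 43 of the latter on the other side of 50. A further 12 returned inside on the same side of 50, 1 returned inside on the other side, and 7 moved outside. Of the balances of single named genes, 106 were identical to the main value and 134 differed.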

Other observations

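The test of the 10000 strongest peaks and the balance of gene lists relative to their chromosomes were chosen only after the results they bear on were seen. The ratio with equal numbers of peaks was planned as a test of list length, and the ratio with the stronger 50% of each list as a test of weak peaks; that list lengths keep both from deciding was recognised only after the values were seen.

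A group of genes, chosen after their values were seen and of which the naming rule covers Aldh1l1, carried PPO2-only regions and none of PPO1, against the genome-wide excess of PPO1-only regions. These were 12 genes with at least 3 PPO2-only and 0 PPO1-only regions, out of 6850 genes with at least 1 line-only region. How many such genes would arise by chance was not estimated, and the shares of their chromosomes were not taken into account. Cables1, a regulator of cyclin-dependent kinases, Mettl25, the predicted gene Gm14092 and Ntrk2 had 4 each. Aldh1l1, Ccdc3, Clmn, Olfm1 (a secreted neuronal glycoprotein), Plat (tissue plasminogen activator), Plekha7 (a junction protein), Sil1 (a co-chaperone of the endoplasmic reticulum) and A530032D15Rik, a relative of Sp110, had 3 each. The regions of A530032D15Rik are uncertain for the reason given for Sp110. Ptn, the growth factor pleiotrophin, Tgfbr2, a receptor of TGF-beta, Sema4d and Cpe had 1 PPO1-only and 3 PPO2-only regions.

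Strong peaks were nearly all shared between the lines. Of the 10000 strongest peaks of a list, 3.58% (3.23–3.96) and 3.94% (3.58–4.34) in PPO1 had no peak in either PPO2 list, and 3.05% (2.73–3.41) and 3.24% (2.91–3.61) in PPO2 had none in either PPO1 list. Against the other list of the same line, 0.09% and 1.00% (PPO1) and 0.66% and 2.28% (PPO2) had none. Windows of 10 Mb with at least 20 line-only regions ranged from 32.3% PPO1-only (10 and 21 regions, chromosome 18, 20000001–30000000) to 95.7% (45 and 2 regions, chromosome 13, 1–10000000).

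The excess of PPO1-only over PPO2-only regions, 3.63 to 1, may reflect peak strength or list length. Weak peaks near the authors' threshold stay open: the ratio was 3.69 with the stronger 50% of each list, but those lists keep their length ratio of 1.39 and a threshold of their own, so this value excludes nothing. Low rank in a peak's own list also stays open, as 3.58% and 3.94% of the strongest peaks of the PPO1 lists lacked a counterpart where over 10% would have spoken against it. List length itself cannot be told apart from a real difference, because lists of equal length force the ratio toward 1 and it was 0.999. Depth, the share of reads in peaks and the Cre driver were not tested: the driver differs between the same 2 libraries by their labels, and the others may.

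Over 20 chromosomes the PPO1-only share ranged by 36.5 percentage points, where 1000 random assignments of the line-only regions gave at most 11.2, and with equal numbers of peaks by 43.2 points, where they gave at most 17.2, which argues against counting error and list length as the whole cause. A candidate explanation is a difference in copy number of whole chromosomes or large parts, which changes the reads on all of a chromosome. That predicts windows and region kinds that move together, and across chromosomes, which are not independent replicates, the lower of both correlations was r = 0.711 (gene-end against other regions, 0.512 without chromosomes 15 and 18) and the other 0.919 (odd against even windows of 10 Mb, 0.854 without them). Windows of at least 20 line-only regions lay between 85.0% and 93.9% on chromosome 15, but between 46.2% and 94.7% on chromosome 16, 44.4% and 86.0% on chromosome 7 and 32.3% and 64.8% on chromosome 18, which goes against 1 uniform change over chromosomes 16 and 7 and leaves changes of parts open. Read coverage was not used here, so copy number itself was not measured, and a difference between the lines in regulation across a chromosome stays open.

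The 3 gene lists outside the central 95% of random lists all stayed outside once each gene's balance was taken relative to its chromosome. This argues against differences between whole chromosomes as the whole cause. Position within a chromosome stays open, because 1 share was used per chromosome. Windows of chromosome 16, for example, ran from 46.2% to 94.7%. For the Hox list a part played by whole chromosomes also stays open. That list returned inside (percentile 96.2) without genes on chromosomes 15 and 18, a setting that also leaves fewer genes. List length is a candidate explanation for those calls, as the mesenchymal, Hox and kinase lists had percentiles of 54.7, 94.9 and 12.5 with equal numbers of peaks. A difference in lineage state between the Olig1 and Olig2 lines was not tested, since each line has 1 sample.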
